A study of Nicotiana tabacum with 12 samples.

How the data were processed

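Polyadenylated RNA of the aerial parts of tobacco seedlings was sequenced with paired-end reads of 150 bp, at a minimum of 38 M reads per sample per the labels' protocols. The 12 samples form 4 groups of 3, control and induced at 4 h and control and induced at 48 h, taken from the sample titles. Each sample carries a replicate number in its title and another in its description, here called the library number. Control replicates 1, 2 and 3 have library numbers 4, 3 and 2, and induced replicates 1, 2 and 3 have 2, 3 and 4. Comparisons used only samples whose group the titles give.

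The authors deposited a table of all genes for each time point, with 44403 genes at 4 h and 42659 at 48 h, and a shorter table of higher genes for each. The unit of the deposited per-library values is a signal, found from the values: within a library every value is a whole multiple of 1 step, as gene read counts divided by a factor of that library would be, and the 2 tables were scaled separately by the authors. The ratio columns of the deposited tables equal the mean of the induced over the mean of the control columns, a linear fold. The deposited p-value columns equal an equal-variance two-sided test on the untransformed values without adjustment. The deposited tables of higher genes hold the genes with a fold of at least 1.5 and an unadjusted p under 0.05 (166 at 4 h and 604 at 48 h), some with a description. The authors' test at 48 h counted the repeated library as 2 samples, and with it counted once 225 of the 604 genes still meet the rule. Per the submitters' processing notes edgeR was used, with no version given. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. Few genes are at 0 in any library, so a filter on detection appears to have preceded the deposit.

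Dividing each value by its library's step gave whole reads for 100% of the values within a tolerance of 0.01. Single entries above 5000 and more than 20-fold above the gene's median were taken as inflated, and the genes concerned (4 at 4 h, 14 at 48 h) were left out in all libraries. They held up to 69% of the reads of a library. Control replicate 1 held few recovered reads at both times and is called shallow here. From the other libraries 4504 genes at 0 were expected in it at 4 h and 106 were found, and 2280 were expected at 48 h and 41 found. Genes expected at under 0.5 reads there had 2.38 times the expected reads at 4 h and 2.48 times at 48 h, so its values for low genes are too high. Of its counts from 1 to 20, 46% at 4 h and 49.4% at 48 h were even, against 68.4% to 74.7% in the other libraries, and its inflated entries at 4 h held 0.0501 of the reads of those in control replicate 2. The tables do not settle whether it was sequenced to a low depth or processed otherwise, so its read total is not a certain measure of depth. Control replicates 2 and 3 at 48 h hold identical reads and were used once. Precision was set by the value of 1 recovered read, 0.697 and 0.28 in the shallow libraries and 0.0152 to 0.0322 in the others.

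The tests fixed before the data were examined assumed raw counts and edgeR. The deposited values are not counts, so the test was limma with an intensity trend and robust moderation on log2(value + 0.5), with genes kept at a value of at least 1 in 3 libraries (37238 genes at 4 h, 31565 at 48 h). Log2 fold changes are on that scale and understate the change of low genes. The difference between the effects and the change in control seedlings over time were fitted jointly on the recovered reads of genes in both tables, scaled by TMM to CPM, with the same transformation (41261 genes). P-values were adjusted by Benjamini-Hochberg and called at 0.05. R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0 were used.

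The library numbers were checked as pairs from the deviations of libraries from their group means. Libraries with the same number correlated at 0.16, 0.22 and 0.18 across 19703 genes at 4 h and at 0.54 and 0.47 across 11369 genes at 48 h, and other pairings at 4 h at -0.18 to 0.03. At 48 h the 2 distinct controls deviate as mirror images, so the other pairings there were -0.54, -0.47, -0.11 and 0.11 by construction. The pair of number 3 shares its title number too and does not favour either numbering. The library numbers were therefore taken to pair the samples and the paired value is given where it changes a call or a count by more than 1.5 times, while the title numbers were run as another block. At 48 h only 2 pairs remain, so the paired fit there leaves very little spread within each gene. Its p-values draw largely on spread that limma shares across genes.

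Gene names came from the descriptions in the authors' deposited tables and from symbols of the RefSeq gene table of the assembly ASM71507v2, which was used for names only and whose coordinates were not used. Of the 45034 genes in the deposited tables, 39993 matched it by name, 431 had a description and 1455 a name of either kind. Named genes followed a rule fixed before the data were examined. At each time the 8 largest changes in each direction were taken among genes past the threshold, without overlap between groups, with a mean log2 CPM of at least 0 and a description or symbol, together with up to 3 genes of smallest p in each fixed list. For the difference and for control seedlings over time 4 in each direction were taken. The same rule was also applied to the paired fit, with every pair changed in the same direction in place of no overlap. That use was not part of the fixed rule, and it alone brought in genes such as PMT1, A622, rps7 and the abscisic acid genes named below. Genes named beyond these are list members that passed when paired, or are marked in the text.

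The 23 lists fixed before the data were examined were matched on names and tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, where at least 5 members were measured. A further 14 lists were added after the values were seen, on nicotine, abscisic acid, plastid-encoded and mitochondrion-encoded genes, transporter genes known from roots, and themes of the fixed lists matched on gene symbols.

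Alternatives planned before the data were examined were RLE scaling, library size alone, no filter, a CPM filter, DESeq2 on the recovered reads, leaving out each library, blocks by title or library number, both times in 1 fit and a test against a log2 fold change of 1. Added after the values were seen were edgeR and limma voom on the recovered reads, pseudocounts of 0.25 and 1, a mean value of at least 5, the repeated library counted as 2, organelle genes left out, list members outside the deposited tables, and edgeR without the shallow libraries. Their effects are in the closing section. At 48 h, leaving out either control leaves 1 control library there. Counts of genes from such fits appear only in the closing section, as low ends of ranges and for edgeR without the shallow libraries. Such counts, and a call that ended in such a fit, may reflect the lost sample.

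The procedures were tested on simulated data with 200 changed genes of known fold and the real means and depths. At 4 h limma recovered 6.1%, 30.3% and 75.4% of genes changed 1.5-fold, 2-fold and 4-fold among 37200 genes, with 0% false calls. At 48 h it recovered 12.5%, 37.9% and 98.2% among 31361 genes, with 5.3% false calls. Those runs had no pair effects. With simulated pair effects of SD 0.3 (log2), the unpaired limma fit recovered 0%, 0% and 66.7% at 4 h and 0%, 1.5% and 69.4% at 48 h, with 0% false calls at either time. The fit of the difference recovered 1.5%, 14.9% and 74.2% among 41128 genes, with 1.6% false calls. With pair effects the paired fit at 4 h recovered 3%, 33.8% and 83.3% with 2.5% false calls among 37232 genes. At 48 h the paired fit made 22.1% false calls with pair effects and 31.7% without. The edgeR fit made 15.2% false calls at 4 h and 12.1% at 48 h without pair effects, and 1.7% and 0% with them. The simulation does not model the filter on detection. Its spread was estimated from the real libraries without pairs, so it already holds spread between pairs. The simulated pair effects came on top, so those runs hold more spread than the data. Each setting rests on a single draw. Columns of per-library values in the tables of higher genes were not used, because the 48 h sheet carries the column names of the 4 h libraries.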

Results

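Messenger RNA was sequenced from the aerial parts of seedlings of tobacco (Nicotiana tabacum, cultivar Petit Havana SR1). The stable lines carried AmMIXTA, a MYB transcription factor gene of snapdragon known for shaping the conical cells of the petal epidermis, behind a promoter that β-estradiol switches on. The study asked which genes respond early when glandular trichomes, the secreting hairs of the epidermis, are initiated, and which respond later as cells take on that fate, on cotyledons that normally bear none. Control and induced seedlings were collected after 4 h, at 7 days of age, and after 48 h, at 9 days, with 3 libraries in each of the 4 groups and 15 seedlings per collection. Seedlings given estradiol without the transgene were not analysed here, and neither was the level of AmMIXTA itself, so a response to estradiol cannot be separated from a response to AmMIXTA.

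The deposited values were whole reads divided by a factor of each library. The reads behind them, without the genes left out for inflated entries, ranged from 12457701 to 30103266 per library except in control replicate 1 of either time point, which held 917871 reads at 4 h and 1240033 at 48 h. One read was worth a normalised value of 0.697 and 0.28 in those libraries and 0.0152 to 0.0322 in the others, so low genes were measured coarsely in them. These libraries are called shallow below, but the tables do not settle whether they were sequenced to a low depth or processed otherwise. Control replicates 2 and 3 at 48 h held identical reads in 42659 of 42659 genes. They were counted as 1 sample, which leaves n = 2 for the 48 h control. Replicates are those the labels declare, and the p-values measure only the spread between these samples, which may be technical.

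**Figure D1:**
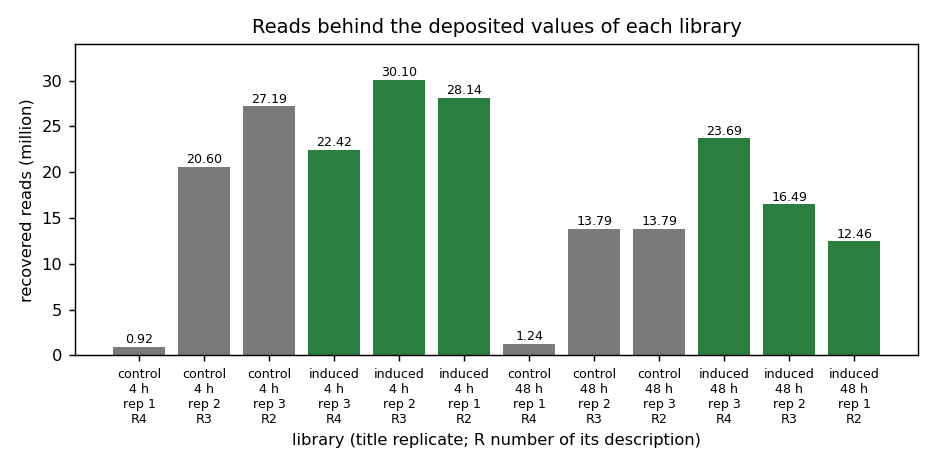
Bars give the number of recovered reads (y axis, in M, from 0) for each library (x axis, named by group, time, title replicate and library number), in grey for control and green for induced seedlings. Control replicate 1 held 917871 reads at 4 h and 1240033 at 48 h, and control replicates 2 and 3 at 48 h both held 13786982 reads because they are identical.

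The first comparison asked which genes respond within 4 h of induction. Genes of nicotine synthesis and transport stood out among those that rose. Nicotine is the main alkaloid of tobacco, known to be made in roots and carried to the leaves. BBL2.1 (LOC107791775), a berberine bridge enzyme-like protein that acts late in nicotine synthesis, rose from a normalised value of 0.962 ± 0.375 to 6.33 ± 2.31 (SD, n = 3 per group), a log2 fold change of 2.20 (SE 0.24, adjusted p = 8.86e-05 by limma). Its relative BBL2.2 (LOC107830440) rose from 1.18 ± 0.801 to 5.07 ± 0.875 (log2 fold change 1.82, SE 0.27, adjusted p = 0.00833). PMT2 (LOC107799426), a putrescine N-methyltransferase that commits putrescine to the pathway, rose from 0.352 ± 0.308 to 2.71 ± 1.14 (log2 fold change 1.90, SE 0.30, adjusted p = 0.00245). NtMATE2 (LOC107807968), a transporter that loads nicotine into the vacuole, rose from 0.942 ± 0.455 to 4.1 ± 1.43 (log2 fold change 1.68, SE 0.26, adjusted p = 0.00286). MPO1 (LOC107807126), a methylputrescine oxidase, rose from 1.38 ± 0.634 to 3.31 ± 0.503 (log2 fold change 1.06, SE 0.22, adjusted p = 0.0247).

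Enzymes that supply the pyridine ring of nicotine rose as well. A quinolinate synthase (LOC107813484) went from 9.31 ± 1.87 to 21.3 ± 5.67 (SD, n = 3 per group, log2 fold change 1.13, SE 0.19, adjusted p = 0.0434 by limma), and a second copy (LOC107817199), named here after its values were seen, had a log2 fold change of 0.93 (adjusted p = 0.0111). A nicotinate-nucleotide pyrophosphorylase (LOC107820078) went from 5.62 ± 0.722 to 9.48 ± 1.84 (log2 fold change 0.69, SE 0.15, adjusted p = 0.0324). Of the 6 measured members of the fixed list of root and alkaloid genes, 2 rose over all genes tested, PMT2 and the pyrophosphorylase, and 6 rose adjusted over the list alone, with a median log2 fold change of 2.11. Camera gave the list an adjusted p of 3.16e-18 with a preset correlation, an adjusted p = 0.0305 with an estimated correlation, and an adjusted p = 0.0754 with an estimated correlation when libraries were paired by number. Its adjusted p lay between 1.47e-28 and 0.0305 when any other setting was changed alone. Since 4 of the 6 members stand in the authors' deposited table of higher genes at 4 h, the list is not independent evidence of its direction. In the paired fit 5 of the 6 rose, among them PMT1 (LOC107771646, log2 fold change 2.32, adjusted p = 8.8e-06 against 0.771 unpaired) and A622 (LOC107784748, a reductase needed for nicotine, 2.48, adjusted p = 0.00281 against 0.791). Over all their alternatives the adjusted p ranged from 3.6e-06 to 1 for PMT1 and from 2.57e-05 to 1 for A622. PMT, BBL and A622 genes are near-identical families, so the split of reads among their copies is uncertain. A set of 4 transporter genes known from roots, chosen after the values were seen, was also higher in induced libraries. Its mean log2 values were 1.74, 1.84 and 2.03 in control and 2.12, 2.31 and 2.34 in induced libraries, and none of the 4 passed the threshold. In induced libraries it kept the order of the 19 nicotine genes measured. Among controls it did not, since replicate 1 was highest for the nicotine genes (1.85) and lowest for the transporters (1.74).

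Single libraries and the choice of fit decided these calls. The calls of BBL2.1 (LOC107791775) and NtMATE2 (LOC107807968) held whichever library was left out and that of PMT2 (LOC107799426) held without each control library, while without an induced library PMT2 missed the filter and was not tested. These 3 calls ended with both times in 1 fit (log2 fold changes then 2.33, 2.16 and 1.81) and by voom (2.94, 3.49 and 2.37). The 1 fit also ended the calls of the other 5 nicotine genes named here, BBL2.2 (1.94), MPO1 (1.14), the quinolinate synthases (1.14 and 0.93) and the pyrophosphorylase (0.70). By edgeR the calls of the synthases (1.30 and 0.99) and the pyrophosphorylase (0.67) ended, by DESeq2 that of the pyrophosphorylase (0.69), by voom those of LOC107817199 (0.96) and the pyrophosphorylase (0.63), and for LOC107813484 also with RLE scaling (1.13) or library size alone (1.14). Without control replicate 3 the calls ended for BBL2.2 (LOC107830440, log2 fold change then 1.72), MPO1 (LOC107807126, 1.01), the quinolinate synthases (LOC107813484, 1.15, and LOC107817199, 0.93) and the pyrophosphorylase (LOC107820078, 0.77). Without control replicate 2 they ended for MPO1 (0.86), both quinolinate synthases (0.99 and 0.91) and the pyrophosphorylase (0.70), and without induced replicate 3 for BBL2.2 (1.77), the synthases (1.14 and 0.91) and the pyrophosphorylase (0.61). Without control replicate 1 they ended for LOC107817199 (0.94) and the pyrophosphorylase (0.60), without induced replicate 1 for MPO1 (0.97) and the pyrophosphorylase (0.62), and without induced replicate 2 for MPO1 (1.06).

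**Figure D2:**
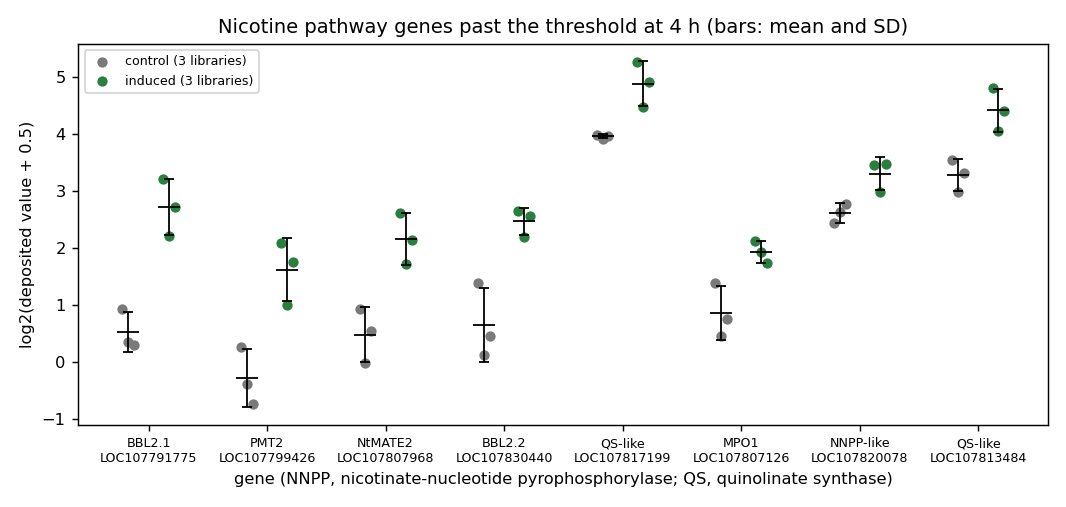
Points are the 3 control libraries (grey) and the 3 induced libraries (green) at 4 h for 8 nicotine pathway genes (x axis), on the scale of log2 of the deposited value plus 0.5 (y axis), with black bars for the mean and SD. In each of the 8 genes every induced library lies above every control library, and the log2 fold changes run from 0.69 to 2.20.

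Single cell wall and auxin genes also rose at 4 h. Extensin-3-like (LOC107826255), a structural cell wall glycoprotein, rose from 4.49 ± 0.942 to 15.9 ± 5.73 (SD, n = 3 per group, log2 fold change 1.68, SE 0.24, adjusted p = 0.0257 by limma). Non-classical arabinogalactan protein 31-like (LOC107813352) rose by a log2 fold change of 0.92 (SE 0.18, adjusted p = 0.014). These were the 2 of 6 cell wall genes past the threshold over all genes. Adjusted over the list alone, 4 were higher and 1 lower, the median was 0.42, and camera gave an adjusted p of 0.000103 with a preset correlation and an adjusted p = 0.0895 with an estimated correlation (5.99e-07 to 0.0895 over its alternatives). Of the 5 auxin genes, 2 rose, both auxin-induced protein 15A-like members of the SAUR family of early auxin-response genes (LOC107818257, log2 fold change 0.77, SE 0.14, adjusted p = 0.00621, and LOC107825512, 0.97, SE 0.19, adjusted p = 0.0324). In the paired fit 3 rose. Adjusted over the list alone 4 were higher, the median was 0.77, and camera gave 2.31e-08 with a preset correlation and an adjusted p = 0.0305 with an estimated correlation (0.0754 when paired, 4.33e-10 to 0.0305 with other single changes). In these lists 2 of the 6 cell wall genes and 4 of the 5 auxin genes come from the authors' deposited table of higher genes, so neither direction is independent evidence. Outside it the median was 0.14 for cell wall genes, and the auxin gene left, SAUR68-like (LOC107823924), had a log2 fold change of 0.01. PTI6-like (LOC107782024), a transcriptional activator of pathogenesis-related genes, rose from 1.05 ± 0.32 to 2.6 ± 0.502 (log2 fold change 1.01, SE 0.22, adjusted p = 0.0334) and was the 1 of 6 defence genes to do so. The defence list had a median of 0.04 and an adjusted p of 0.161 by camera (0.00556 to 0.968 over its alternatives).

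Zinc finger protein 8-like (LOC107828820), related to regulators of trichome formation in thale cress, was the 1 measured gene whose name matched the list of epidermal and trichome regulators. It stands in the authors' deposited table of higher genes at 4 h, so its direction is not independent evidence. It went from 3.03 ± 0.818 to 5.44 ± 0.526 (SD, n = 3 per group, log2 fold change 0.77, SE 0.17), which missed the threshold unpaired (adjusted p = 0.0505 by limma) and passed it paired (0.00218, with a range of 0.00218 to 1 over its alternatives). The other fixed lists had too few named genes for a test at 4 h. Their counts are of genes with a matching name, and genes of these kinds without a name may have been measured. The cytokinin, ethylene and ribosomal protein lists had 3 measured members each, and the gibberellin and glutathione transferase lists 2 each. The ribosomal list was fixed for cytosolic proteins but also matched a 60S L6, mitochondrial-like and a 30S S16-like name. The lists for lipid transfer proteins, acyl sugar precursors, the mitotic cell cycle, DNA replication, flavonoids, vascular tissue, jasmonate and the circadian clock had 1 each, and those for cuticle and wax, trichome terpenoids, photosynthesis and stomata had 0. No gene of these lists passed limma's threshold over all genes in the unpaired fit, while in the paired fit histidine kinase 3-like fell in the cytokinin list and 60S ribosomal protein L26-1-like rose in the ribosomal list.

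With both times in 1 fit the calls of extensin-3-like (LOC107826255, 1.70), LOC107813352 (0.95), LOC107818257 (0.77), LOC107825512 (0.99) and PTI6-like (LOC107782024, 1.09) all ended. Those of the last 4 also ended by DESeq2 (1.08, 0.77, 0.96 and 1.14), edgeR (1.07, 0.76, 0.94 and 1.12) and voom (1.02, 0.75, 0.89 and 1.08), and that of extensin-3-like by edgeR without control replicate 1 (2.01). Without single libraries several of these calls ended in the same way. Extensin-3-like (LOC107826255) lost its call without control replicate 2 or 3 (log2 fold change 1.60 in both) or induced replicate 1 (1.74). LOC107813352 lost it without control replicate 1 or 3 (0.90 in both), induced replicate 1 (0.83) or induced replicate 3 (0.81). LOC107818257 lost it without control replicates 1 (0.70) or 3 (0.73) and induced replicates 1 (0.67) or 3 (0.72). LOC107825512 lost it without control replicates 1 (0.80), 2 (1.04) or 3 (1.07) and induced replicates 1 (0.92) or 2 (0.80). PTI6-like (LOC107782024) lost it without control replicates 1 (0.83) or 3 (1.06) and induced replicates 1 (0.88) or 3 (1.04).

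The genes that fell at 4 h mostly had no name, because descriptions came from the authors' deposited tables of higher genes. LOB domain-containing protein 40-like (LOC107799348), of a plant family of transcription factors, fell from 2.28 ± 0.18 to 0.6 ± 0.227 (SD, n = 3 per group, log2 fold change -1.35, SE 0.23, adjusted p = 0.0027 by limma). It met the filter only through its controls, so without any 1 control library it was not tested. In the shallow control 1 read was worth 0.697, so its value there rests on few reads. Chaperone protein dnaJ 11 (LOC107759587) fell from 21 ± 3.08 to 11 ± 2.33 (log2 fold change -0.91, SE 0.15, adjusted p = 0.00529), without control replicate 1 (-0.87) or 3 (-0.84), by edgeR (-0.91) or by voom (-0.91) no longer past the threshold. It was the 1 of 5 heat shock and chaperone genes to fall, and that list had a median of -0.13 and an adjusted p of 0.13 by camera (0.017 to 0.465 over its alternatives). The mitochondrial gene cox1 (NitaMp049), a subunit of cytochrome oxidase, fell from 4.27 ± 0.152 to 2.04 ± 0.356 (log2 fold change -0.92, SE 0.17, adjusted p = 0.00758), not past the threshold without control replicate 1 (-0.93), with both times in 1 fit (-0.97) or by DESeq2 (-1.08). Mitochondrion-encoded genes held 0.202% to 0.23% of the reads in control and 0.165% to 0.195% in induced libraries, and plastid-encoded genes 6.57% to 7.4% against 4.57% to 5.84%. Polyadenylated RNA was sequenced, and whether such reads follow the levels of organelle transcripts was not tested. Of unnamed genes, chosen here after their values were seen, LOC107772048 fell from 54.8 ± 5.66 to 8.94 ± 0.622 (log2 fold change -2.55, SE 0.11, adjusted p = 5.63e-13) and LOC107797524 from 25.1 ± 2.17 to 3.85 ± 0.683 (log2 fold change -2.57, SE 0.13, adjusted p = 7.63e-12). Both passed the threshold in all 22 alternatives run for them.

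Across the transcriptome, 131 of 37238 genes passed an adjusted p of 0.05 by limma at 4 h, 36 higher and 95 lower, and 9 and 40 of these reached a log2 fold change of 1. In each of the 131 genes the libraries of the groups did not overlap. Among all genes tested, 2029 were higher and 1844 lower without overlap, where chance gives 10%. Pairing libraries by number gave 376 genes (161 higher, 215 lower), and leaving out control replicate 1 gave 85 (22 higher, 63 lower). With both times in 1 fit 52 genes passed (4 higher, 48 lower), so most higher calls ended there. On the recovered reads edgeR called 93 genes (19 higher, 74 lower).

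The second comparison asked which genes respond after 48 h, when cells are thought to take on the trichome fate. Few genes passed. Heat stress transcription factor B-2b-like (LOC107823244), of a class of heat shock factors known mostly as repressors, rose from 7.79 ± 1.52 (SD, n = 2) to 19.3 ± 0.548 (SD, n = 3), a log2 fold change of 1.27 (SE 0.14, adjusted p = 0.000449 by limma). The other genes past the threshold had no name and are given because they were so few. LOC107782728, annotated as a long non-coding RNA, rose from 15.5 ± 0.579 to 42.8 ± 4.67 (log2 fold change 1.43, SE 0.13, adjusted p = 8.37e-05). LOC107809507 rose by 1.06 (SE 0.15, adjusted p = 0.0136) and LOC107781399 had a log2 fold change of -0.81 (SE 0.13, adjusted p = 0.0442). By voom no gene passed, with log2 fold changes of 1.16 for LOC107823244 and 1.46 for LOC107782728. With both times in 1 fit and by edgeR the calls of LOC107809507 (1.10 and 1.01) and LOC107781399 (-0.83 and -0.87) ended. Blocked by title number with the repeated library as number 3, none of these calls held. The log2 fold changes were then 1.29 for LOC107823244, 1.44 for LOC107782728, 1.13 for LOC107809507 and -0.82 for LOC107781399. By edgeR without control replicate 1, which leaves 1 control library, LOC107823244 had a log2 fold change of 1.12. The call of LOC107809507 ended without control replicate 1 (0.89) or induced replicate 1 (1.08), and that of LOC107781399 without control replicate 1 (-0.84), control replicate 2 (-0.79) or induced replicate 1 (-0.85).

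Of the fixed lists, cell wall and heat shock genes had positive medians at 48 h, but no member passed limma's threshold over all genes. The 6 cell wall genes had a median log2 fold change of 0.49, with 1 higher adjusted over the list alone, an adjusted p of 0.00159 with a preset correlation and an adjusted p = 0.084 with an estimated correlation (5.09e-08 to 0.084 over its alternatives). The 6 heat shock and chaperone genes had a median of 0.37, with 1 higher adjusted over the list alone, 0.00457 with a preset correlation and an adjusted p = 0.084 with an estimated correlation (0.000438 to 0.255 over its alternatives). Without control replicate 1 the heat shock list no longer passed (0.255), and without any 1 induced replicate the cell wall list had under 5 members and was not tested. Paired by library number, 2 cell wall genes and 1 heat shock gene rose over all genes, and both lists had an adjusted p = 0.262 with an estimated correlation. The 5 defence genes had a median of 0.01 and an adjusted p of 0.291 (0.0871 to 0.79 over its alternatives). In the cell wall and in the heat shock list 3 of the 6 genes stand in the authors' deposited table of higher genes at 48 h. The medians outside it were 0.35 and 0.03, so neither direction is independent evidence. Lists too small for a test at 48 h were auxin with 4 members, cytokinin and ribosomal proteins with 3, root and alkaloid, glutathione transferase, gibberellin and ethylene with 2, and trichome regulators, lipid transfer, acyl sugar precursors, DNA replication and circadian clock with 1. None of their genes passed limma's threshold over all genes unpaired, while paired by library number SAUR32-like (auxin), histidine kinase 3-like (cytokinin), the gibberellin receptor GID1B-like and the ethylene-responsive factor TINY-like each rose. Zinc finger protein 8-like (LOC107828820) had a log2 fold change of -0.55 (adjusted p = 0.803, and 0.0301 paired, 0.0301 to 1 over its alternatives).

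In total 4 of 31565 genes passed at 48 h, 3 higher and 1 lower, while 1090 higher and 772 lower genes had an unadjusted p under 0.05. Genes without overlap between the groups numbered 3947 higher and 2817 lower, where chance gives 20%. Scaling by library size alone gave 8 genes (3 higher, 5 lower). Leaving out induced replicate 3 gave 61 genes (33 higher, 28 lower) and leaving out induced replicate 2 gave 46 (41 higher, 5 lower). Pairing by library number, which rests on 2 pairs, gave 429 genes (273 higher, 156 lower), but in simulated data of this layout 22.1% to 31.7% of the paired calls were false against a nominal 5%.

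The third comparison asked whether the response differed between 48 h and 4 h. LOB domain-containing protein 40-like (LOC107799348) had log2 fold changes of -1.51 after 4 h, which passed, and 1.05 after 48 h, which did not (adjusted p = 0.217), in the joint fit (difference 2.57, SE 0.36, adjusted p = 0.00122 by limma). Heat stress transcription factor B-2b-like (LOC107823244) went from -0.38 to 1.31 (difference 1.69, SE 0.23, adjusted p = 0.00122). XERICO (LOC107822042), a ubiquitin ligase known to raise abscisic acid levels, went from -0.51 to 1.00, and cox1 (NitaMp049) from -0.97 to 0.52. Copies of cytochrome P450 85A1, an enzyme of brassinosteroid synthesis, went the other way, from 0.91 to -1.07 in LOC107776096 (difference -1.98, SE 0.36, adjusted p = 0.0153) and from 0.75 to -0.95 in LOC107760973. So did basic leucine zipper 61-like (LOC107777300), from 0.80 to -0.66, and aspartic proteinase PCS1-like (LOC107786388), from 0.66 to -0.76. Of the 48 h effects in this paragraph only that of LOC107823244 passed by itself in the joint fit, and of the 4 h effects those of LOC107799348 and LOC107777300.

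**Figure D3:**
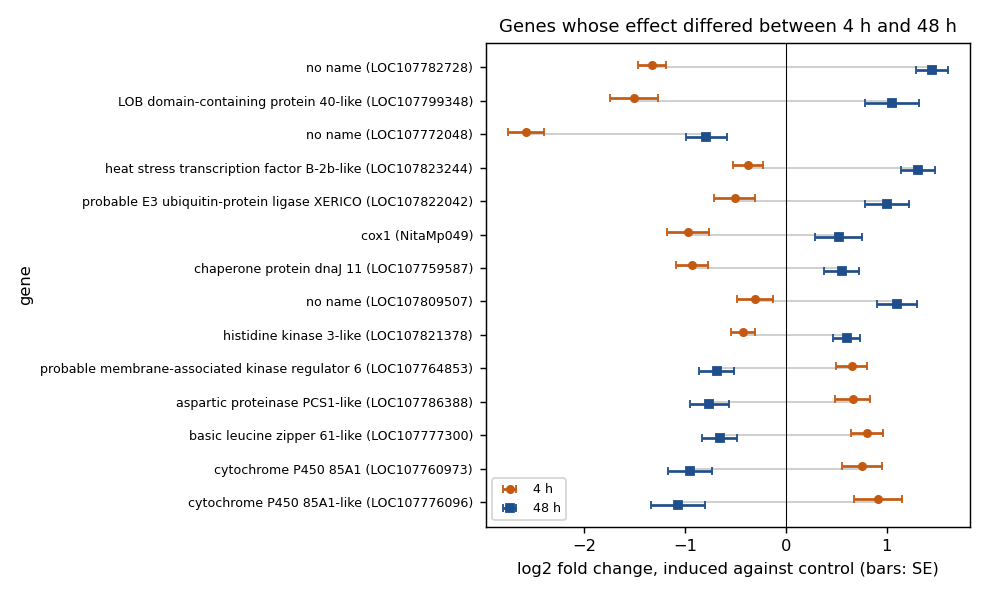
Each line joins the log2 fold change of induced against control seedlings (x axis) at 4 h (orange circles) and 48 h (blue squares) for a gene (y axis) whose effects differed in the joint fit, with bars for the SE. LOC107782728 goes from -1.33 to 1.45 and LOB domain-containing protein 40-like from -1.51 to 1.05, while cytochrome P450 85A1-like goes from 0.91 to -1.07.

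Without single libraries some of these differences no longer passed. XERICO (LOC107822042) failed without control 4 h replicate 3 (1.27), induced 4 h replicates 2 (1.37) or 3 (1.5), control 48 h replicate 2 (1.36) and induced 48 h replicates 1 (1.47) or 3 (1.5). That of cox1 (NitaMp049) failed without control 4 h replicates 1 (1.49), 2 (1.45) or 3 (1.48), induced 4 h replicates 1 (1.5), 2 (1.36) or 3 (1.60), control 48 h replicate 1 (1.10) and induced 48 h replicates 1 (1.28) or 2 (1.52). LOC107776096 failed without control 4 h replicate 3 (-1.91), induced 4 h replicate 1 (-1.98) or control 48 h replicate 2 (-1.74), and LOC107760973 without control 4 h replicate 1 (-1.62) or control 48 h replicate 2 (-1.74). PCS1-like (LOC107786388) failed without induced 4 h replicates 1 (-1.43) or 2 (-1.37) or control 48 h replicate 2 (-1.26). Those of LOC107799348, LOC107823244 and LOC107777300 passed whichever single library was left out, but by edgeR without both shallow libraries those of LOC107777300 (-1.42), LOC107822042 (1.97), LOC107760973 (-1.75) and cox1 (1.23) ended.

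The effects differed in 66 of 41261 genes by limma, 44 with a positive and 22 with a negative difference. Of the 66, 36 went from a negative to a positive log2 fold change, 22 from positive to negative, and 8 kept their sign. The count was 35 without control 4 h replicate 1, 40 without control 4 h replicate 3 or induced 4 h replicate 3, and 41 without induced 4 h replicate 1. Scaling by library size alone gave 48 genes (23 positive, 25 negative), and pairing by library number gave 343 (198 positive, 145 negative).

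The responses at 4 h and 48 h shared 1 gene, in opposite directions. LOC107782728, the long non-coding RNA that rose at 48 h, fell at 4 h from 15.2 ± 3.53 to 5.84 ± 1.04 (SD, n = 3 per group, log2 fold change -1.30, SE 0.15, adjusted p = 9.49e-05 by limma). No gene passed at both times in the same direction by limma, or by DESeq2, among 31383 genes tested at both. At an unadjusted p under 0.05 at both times, 243 genes were found and 164 of them moved in opposite directions. Across genes the log2 fold changes had a Pearson correlation of -0.037 and a Spearman correlation of -0.02, and genes are not independent replicates. Paired by library number, 12 genes passed in the same direction, 4 of them higher and 8 lower at both times (1.02 and 0.946 expected from independent lists, two-sided Fisher's exact p = 0.0197 and 5.31e-06). In opposite directions, 20 passed as higher then lower (0.634 expected, two-sided Fisher's exact p = 1.69e-24) and 27 as lower then higher (1.53 expected, p = 9.39e-26). Blocked by title number the balance turned, with 14 genes in the same direction, 13 of them lower at both times (0.297 expected, p = 3.02e-18), against 5 in opposite directions and a Pearson correlation of 0.04. The comparisons have no library in common. In simulated data the fit paired by library number at 48 h exceeded its nominal share of false calls, as given above. Genes called at both times and blocks by title number were not simulated, so the false share of these counts is not known. Fisher's test takes genes as independent, which genes of the same libraries are not, so its p-values do not measure evidence from replicates. At an unadjusted p under 0.05 at both times, 4 of 8 pairs of splits that part all pairs were as one-sided as the real pair.

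Control seedlings at 48 h were compared with those at 4 h as a background for growth over the same interval. B-box zinc finger protein 19-like (LOC107807066), of a family that acts in light signalling, rose from a mean of 1.53 to 21.9 CPM after scaling (log2 fold change 3.48, SE 0.21, adjusted p = 4.2e-11 by limma). Ninja-family protein AFP3-like (LOC107799287), of a family that binds abscisic acid response factors, rose from 1.39 to 17.6 (3.20, SE 0.40, adjusted p = 0.000342). Rca (LOC107819807), rubisco activase, had a log2 fold change of 2.50 (SE 0.42, adjusted p = 0.00798) and IPS (LOC107766502) of 2.34 (SE 0.51, adjusted p = 0.0256). Copies of an F-box protein At2g16365-like fell by 3.6 (LOC107768020, SE 0.30, adjusted p = 1.83e-05) and fell by 2.94 (LOC107808647, SE 0.21, adjusted p = 7.13e-10) on the log2 scale. SCP1 (LOC107824458) had a log2 fold change of -2.56 (SE 0.33, adjusted p = 5.05e-05) and inositol transporter 4-like (LOC107823152), which moves inositol across membranes, of -2.29 (SE 0.30, adjusted p = 5.41e-06). The call of Rca ended without control 48 h replicate 2 (2.11), and that of IPS by edgeR without the shallow libraries (2.31) and without control 4 h replicates 1 (2.16) or 2 (2.06) or control 48 h replicates 1 (2.67) or 2 (2.00). In all 5025 genes changed, 2345 higher and 2680 lower, and 3645 without control 4 h replicate 2. Without control 48 h replicate 2 the only control left at 48 h is the shallow one, so its count is not used here. Age, time of collection and any batch cannot be told apart in this comparison.

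The authors' deposited tables of higher genes were set beside these fits. Of the 166 genes listed at 4 h, 132 were tested and all 132 had a positive log2 fold change, with a median of 0.60. Among them 34 passed the adjusted threshold by limma, BBL2.1, PMT2, NtMATE2 and extensin-3-like included. Of the 604 genes listed at 48 h, 375 were tested, all 375 positive with a median of 0.57, of which 3 passed by limma and 332 had an unadjusted p under 0.05. Paired by library number, 68 of the listed genes passed at 4 h and 112 at 48 h, and DESeq2 called 13 and 12. The p-values of the authors' deposited tables are not adjusted for multiple tests, and after Benjamini-Hochberg adjustment 0 of the 2299 genes under 0.05 at 4 h and 5 of the 5504 at 48 h stayed under 0.05. The tables come from the same libraries and are not independent evidence.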

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

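The test of the 100 pairs of splits was planned before its result was seen, and the tests of the paired splits, of exchanged labels and of the shallow libraries were chosen after.

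Genes stand here because their response to induction differed between the time points by limma, which held for 66 of 41261 genes. LOB domain-containing protein 40-like (LOC107799348), a transcription factor, had log2 fold changes of -1.51 at 4 h and 1.05 at 48 h (adjusted p = 0.217), a difference of 2.57 (SE 0.36, adjusted p = 0.00122). The mitochondrial gene cox1 (NitaMp049) differed by 1.49 (SE 0.31, adjusted p = 0.0492), no longer past the threshold with RLE scaling (1.49) or library size alone (1.41). Chaperone protein dnaJ 11 (LOC107759587) differed by 1.48 (SE 0.23, adjusted p = 0.0083, from -0.93 to 0.55). Heat stress transcription factor B-2b-like (LOC107823244) differed by 1.69 (SE 0.23, adjusted p = 0.00122), and XERICO (LOC107822042), a ubiquitin ligase tied to abscisic acid, by 1.51 (SE 0.29, adjusted p = 0.0255). Histidine kinase 3-like (LOC107821378), of the family of cytokinin receptors, differed by 1.03 (SE 0.18, adjusted p = 0.0109, from -0.43 to 0.60).

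Other genes had positive log2 fold changes at 4 h and negative ones at 48 h, and none of these 48 h effects passed by itself in the joint fit. The brassinosteroid enzymes cytochrome P450 85A1-like (LOC107776096) and cytochrome P450 85A1 (LOC107760973) differed by -1.98 (SE 0.36, adjusted p = 0.0153 by limma) and -1.70 (SE 0.30, adjusted p = 0.0111). Basic leucine zipper 61-like (LOC107777300) differed by -1.46 (SE 0.23, adjusted p = 0.00504), aspartic proteinase PCS1-like (LOC107786388) by -1.43 (SE 0.26, adjusted p = 0.0161) and membrane-associated kinase regulator 6 (LOC107764853) by -1.34 (SE 0.23, adjusted p = 0.00925, from 0.65 to -0.69).

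Genes without a name were chosen after their values were seen. The long non-coding RNA LOC107782728 differed by 2.78 (SE 0.21, adjusted p = 4.46e-07 by limma). LOC107809507 differed by 1.41 (SE 0.27, adjusted p = 0.0338, from -0.31 to 1.10), and paired by library number by 1.44 (adjusted p = 0.165). LOC107772048 differed by 1.79 (SE 0.27, adjusted p = 0.0109, from -2.58 to -0.79), with a fall at 4 h and no call at 48 h, and paired by 1.81 (adjusted p = 0.358).

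In the paired fit at 48 h dnaJ 11 (LOC107759587), LOB domain-containing protein 40-like (LOC107799348), XERICO (LOC107822042) and histidine kinase 3-like (LOC107821378) rose and cytochrome P450 85A1 (LOC107760973), basic leucine zipper 61-like (LOC107777300) and kinase regulator 6 (LOC107764853) fell, with 22.1% to 31.7% of such calls false in simulated data. In the paired fit at 4 h PCS1-like (LOC107786388) rose and histidine kinase 3-like fell. By DESeq2 the differences of cytochrome P450 85A1 (LOC107760973, -1.78), kinase regulator 6 (LOC107764853, -1.28), cox1 (NitaMp049, 1.42) and LOC107809507 (1.36) ended. By edgeR without the shallow libraries those of XERICO (LOC107822042, 1.97), histidine kinase 3-like (LOC107821378, 1.05), cytochrome P450 85A1 (LOC107760973, -1.75), basic leucine zipper 61-like (LOC107777300, -1.42), kinase regulator 6 (LOC107764853, -1.16), cox1 (1.23) and LOC107809507 (1.24) ended. Single libraries decided some of these differences. Those of histidine kinase 3-like (LOC107821378) ended without control 4 h replicate 1 (0.94) or control 48 h replicate 2 (0.93), that of kinase regulator 6 (LOC107764853) without control 48 h replicate 1 (-1.14), and that of LOC107772048 without induced 4 h replicate 3 (1.76). That of LOC107809507 ended without control 4 h replicates 1 (1.34) or 3 (1.24), induced 4 h replicates 1 (1.37) or 3 (1.28), control 48 h replicates 1 (1.23) or 2 (1.58) and induced 48 h replicates 1 (1.43) or 3 (1.30).

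Of 243 genes with an unadjusted p under 0.05 at both times, 67.5% moved opposite ways, and among 100 pairs of a split at 4 h with a split at 48 h, 46 were as one-sided as the real pair, the real pair included (highest other 91.3%). Variation between collections that does not follow the groups stays open as the source, because many of those splits part fewer pairs of libraries than the real one, and with libraries paired by number 4 of 8 pairs of splits were as one-sided (real pair 64.9% of 533 genes, highest other 85.4%), too few for a share under 0.05. The shallow control libraries stay open as the source. EdgeR without them gave 74.1%, but that fit holds 1 control library at 48 h, so the test cannot decide. It replaced an earlier test (79.7% of 59 genes called at both times when paired) after values were seen. Group labels exchanged at 1 time point stay open, because 60.2% of 324 genes called at 4 h in the paired fit changed sign (exact interval 54.6% to 65.6%) and the transgene was not analysed here. A bound of 75% written first was set aside after the value was seen, because genes that respond at 1 time only change sign in about 50% of cases under exchanged labels too.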

How the results depend on the processing

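The scaling, filter, DESeq2, block, leave-out, joint and fold settings were fixed before the data were examined, while edgeR, voom, the pseudocounts, the mean value of 5, the repeated library counted otherwise, members outside the deposited tables and the fits without shallow libraries were chosen after. Of the genes the naming rule chose in the unpaired or the paired fit, only the plastid gene rps7 (NitaCp074) changed sign (-0.90 to 0.43). It was named through the paired fit and was not called unpaired at 48 h. At 4 h 131 genes were called, 85 to 156 with a library left out, 242 blocked by title number, 52 with both times in 1 fit (4 higher, 48 lower), 4 against a log2 fold change of 1, 65 by voom, and 78 by edgeR without the shallow library. At 48 h 4 were called, 3 to 61 with an induced library left out, 8 by library size alone, 17 with the CPM filter and 13 by DESeq2. Blocked by title number the count was 148 (1 with the repeated library as number 3, which was none of the 4). It was 10 in 1 fit, 0 against a log2 fold change of 1, 2 by edgeR, 0 by voom, 11 with a pseudocount of 1 and 2 at a mean value of at least 5. The difference held in 66 genes, 19 to 94 with a library left out, 144 blocked by title number and 31 by edgeR without the shallow libraries. For control seedlings over time it was 5025, 2243 to 5264 with a library left out, 2733 by DESeq2 and 2977 by edgeR without the shallow libraries. Genes past the threshold in the same direction at both times numbered 14 blocked by title number (5 in opposite directions). Of genes in the authors' deposited tables DESeq2 called 13 at 4 h and 12 at 48 h. Of fixed lists 3 passed at 4 h (3 to 4 with a library left out, 5 with the CPM filter, 0 with members outside the deposited tables, where under 5 members were left in each of the 3) and 2 at 48 h (1 to 2 with a library left out, 0 with an estimated correlation). The low ends of the ranges for the difference and for control seedlings over time come from the fit without control 48 h replicate 2. That fit leaves only the shallow control at 48 h, so these low ends may reflect the lost sample. Among fits with a library left out that keep 2 controls at 48 h, the lowest counts were 35 and 3645. The edgeR counts without the shallow libraries for these 2 comparisons also rest on 1 control at 48 h. Where fewer samples or a stricter test do not show the reason, the cause was not tested.

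The paired fit by library number called 376 genes at 4 h (260 at a mean value of at least 5), 429 at 48 h (646 with the repeated library as number 2), 343 for the difference, 12 in the same and 47 in opposite directions at both times, and 68 and 112 of the genes in the authors' deposited tables. It ended the calls of the difference in LOC107809507 (1.44) and LOC107772048 (1.81), ended 3 list calls (mitochondrion-encoded at 48 h, 0.26, and root and alkaloid and auxin at 4 h with an estimated correlation, 0.0754 each), added the calls given beside the genes and lists, and changed no other call given here. RLE scaling moved none of the counts it was run for by more than 1.5 times, nor did a pseudocount of 0.25 at 4 h and 48 h, where alone it was run. Depth, as far as recovered reads measure it, limits what can be called among low genes, since 1 read in the shallow controls was worth 0.697 at 4 h and 0.28 at 48 h.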

Other observations

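The splits of libraries and the fit without organelle genes were planned before their results were seen, while the added lists and the tests of root tissue, jasmonate, the shallow library, organelle genes among the calls and the shift of nuclear genes were chosen after.

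Genes of abscisic acid, the hormone of drought and dormancy, were among the larger changes at 48 h. The paired fit at 48 h rests on 2 pairs, so its small p-values draw largely on spread shared across genes, not on replicates. Paired by library number, limma called ATHB-12-like (LOC107772091, log2 fold change 1.79, adjusted p = 3.11e-16 against 0.835 unpaired) and LOC107765920 (1.73, adjusted p = 2.09e-10 against 0.567), homeobox genes that respond to the hormone. It also called ninja-family protein AFP3-like (LOC107799287, 1.44, adjusted p = 1.1e-12 against 0.867) and AFP1-like (LOC107785798, 2.04, 0.00407 against 0.363). Protein phosphatase 2C 24 (LOC107807989), of the clade that restrains the hormone's signal, had 1.39 (2.18e-05 against 0.0617), and NAC72-like (LOC107771009), a drought-response factor, 1.38 (4.74e-08 against 0.558). Over their alternatives the highest adjusted p of each of these genes was 1. Of the 23 genes of the added list, 20 were positive with a median of 0.90, none passed unpaired by limma over all genes, 15 were higher adjusted over the list alone and 16 passed paired. Camera gave an adjusted p of 1.08e-25 with a preset correlation and an adjusted p = 0.26 with an estimated correlation (0.496 when paired). As 16 of the 23 stand in the authors' deposited table and the median outside it was 0.05, the list is not independent evidence, and in simulated data 22.1% to 31.7% of paired calls at 48 h were false. At 4 h the list of 21 genes had a median of -0.06 (adjusted p = 0.773), with 1 gene higher unpaired and 2 paired.

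Organelle genes had negative medians at 4 h, with 1 gene of each kind past the threshold unpaired. These are reads from polyadenylated RNA, which may not follow the levels of organelle transcripts. The 29 mitochondrion-encoded genes had a median log2 fold change of -0.32, with 1 lower over all genes by limma (cox1), an adjusted p of 4.74e-16 with a preset correlation and an adjusted p = 0.0561 with an estimated correlation (0.266 when paired). The 66 plastid-encoded genes had a median of -0.23, with 1 lower (2 paired), 9.25e-17 and an adjusted p = 0.3 with an estimated correlation (0.608 when paired). At 48 h the medians were 0.22 (0.0107, 0.26 when paired, and 0.897 with an estimated correlation) and 0.05 (0.207, with 2 genes higher and 1 lower when paired). Flavonoid genes matched on symbols had a median of 0.16 at 4 h (0.000113, and 0.147 with an estimated correlation), nuclear photosynthesis genes 0.12 (0.00397 and 0.741) and cell wall genes 0.14 (0.0172 and 0.339), with no member past limma's threshold over all genes unpaired and 1 each paired (CHI, Rca and Nt-EXPA1). In the ethylene list NtERF1 rose when paired. Terpenoid (0.10, adjusted p = 0.287), cell cycle (0.00, 0.773), defence (0.00, 0.773), jasmonate (0.03, 0.773), ethylene (-0.01, 0.287) and ribosomal protein genes (0.09, 0.0524) did not pass as lists at 4 h. At 48 h the medians were 0.02 for nicotine (0.745), 0.05 for photosynthesis (0.39), 0.12 for terpenoid (0.21), 0.06 for cell cycle (0.719), 0.03 for cell wall (0.657), -0.04 for flavonoid (0.245), -0.04 for defence (0.128), -0.02 for jasmonate (0.989), 0.02 for ethylene (0.416) and 0.08 for ribosomal protein genes (0.175). Paired, 1 cell wall gene rose and 1 fell, and 1 gene fell in each of the defence (ACRE1) and ethylene (NtERF4) lists. The list of root transporters had 4 members at 4 h and 3 at 48 h, too few for a test.

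Of 19 nicotine genes measured at 4 h, 19 were positive with a median log2 fold change of 1.30, 8 passed limma's threshold unpaired and 16 paired, and camera gave 6.18e-42 with a preset correlation, an adjusted p = 0.0561 with an estimated correlation and 0.266 when paired (12 of the 19 stand in the authors' deposited table, and the median outside it was 0.88). The tables argue against the shallow control as the source, since the median without it was 1.71. The 8 jasmonate genes did not rise by as much as the nicotine genes (mean 0.06, upper bound 0.2 over genes, not libraries). Their means lay 0.26, -0.03 and -0.07 from the control mean in induced libraries and -0.06 to 0.1 in controls. A jasmonate response before 4 h and a wound response through other genes were not tested. Root tissue in the induced collections stays open, because 4 transporter genes known from roots were all positive with a mean of 0.38 and none past the threshold, though per the labels only aerial parts were collected. A bound at the nicotine median, written first, was set aside after the value was seen, because expression of these genes in shoots would hide a small share of roots. An effect of estradiol or of AmMIXTA was not tested and cannot be separated by these samples.

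More genes passed as lower than as higher at 4 h, 95 of 131 by limma and 215 of 376 in the paired fit, while at an unadjusted p under 0.05 the higher genes were more (1092 against 1046). The tables argue against the values of the shallow control as the whole source (74.1% lower without it). They cannot decide on genes that a filter on detection may have removed before the deposit, since leaving that library out does not bring them back. The tables argue against organelle genes as the excess, since 2 of the 95 lower genes were organelle genes. They argue as well against the larger organelle share of the controls, since 72.9% were lower with organelle genes left out and nuclear reads scaled again, and that share shifts nuclear genes by 0.012 to 0.044 log2 toward higher in induced libraries, against a median of -0.915 in the lower genes. Other sources were not tested.

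Among the 10 splits of the 6 libraries at 4 h, 1, the real one, gave as many as 131 genes, and the highest other gave 19. Paired by library number, 1 of the 4 splits that part all pairs gave as many as 376, and the highest other gave 2. These splits are too few for a share under 0.05.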
